A study of Mus musculus with 14 samples.

How the data were processed

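The series holds 14 two-colour arrays of 12 mammary tumours from Brg1+/- mice. Per the labels, total RNA was extracted with the Qiagen RNeasy kit and labelled after a published protocol, with tumour RNA in Cy5 and a common mouse reference RNA in Cy3 on every array. The deposited series table gives, for each array and probe, a value on a log2 scale, which was read as the log2 ratio of tumour over reference. The direction was taken from the dyes, per the labels. The base of the logarithm is not stated, and base 2 was inferred from the range of the values, -9.19 to 7.42. The array medians lay between 0 and 0.018, so the deposited log2 values look centred per array and not per gene. The scanner, background correction, normalization and spot filters are not given in the sources used here. Pairs of arrays correlated between 0.465 and 0.898 over all probes, so no array ran in the opposite direction. Because all arrays share 1 dye orientation, a dye effect on a gene is part of its ratio against the reference, but cancels in differences between tumours. Two-colour ratios carry no signal level here, so dim probes could not be told from bright ones, and only the number of arrays and missing values describe precision. Of all values 0.172% were missing, and each array had 22501 to 22566 of 22575 probes.

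Probes were named through the platform annotation given for this work, which can be old. Of 22575 probes, 18658 had 1 gene symbol, 30 had several and 3887 had none. Only probes with 1 symbol were used for genes. Symbols were updated through the NCBI RefSeq gene table of assembly GRCm38.p6, which matched 18445 probes by Entrez gene identifier and 24 by accession, and 189 kept the symbol of the annotation. This gave 16879 genes, 1254 of them with more than 1 probe, whose values were averaged. Genes needed a value on at least 12 of 14 arrays and on both arrays of T172 or of T284. This left 16877 genes, of which 16474 had values on all 14 arrays. No further normalization was applied.

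Differences between tumours were tested with limma 3.58.1 in R 4.3.3. A factor of 12 tumours was fitted to all 14 arrays and a moderated F-test compared the tumours with the spread within a tumour, which came from the second arrays of T172 and T284. The prior had 7.27 degrees of freedom and an SD of 0.313. Each tumour was then compared with the mean of the other 11 by limma's moderated test, with the 2 arrays of T172 and of T284 averaged first. The lone tumour is there assumed to vary like the other 11. P-values were adjusted after Benjamini-Hochberg, within each tumour for this comparison, and a gene was called at an adjusted p under 0.05.

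The comparisons, the 19 gene lists (315 genes, 293 measured), the 15 relations, most alternatives and the rule for naming genes were set before the data were examined. The lists cover luminal, basal and squamous epithelium, smooth muscle, junctions, mesenchymal and matrix genes, proliferation, SWI/SNF subunits, lymphocytes, macrophages, interferon response, adipocytes, endothelium, milk, skeletal muscle, p53 targets, hypoxia, and immediate early and heat shock genes. Each list was compared with all other genes for the share of calls (two-sided Fisher's exact test) and for its mean pairwise correlation against 10000 random lists. Each list was also tested in each tumour with camera at an inter-gene correlation of 0.01, adjusted over 228 combinations, with the estimated correlation as an alternative. A list score is the mean over members of the log2 ratio minus the gene's mean over 12 tumours. Relations between scores used Pearson's r and Spearman's rho with 100000 resamples each. The similarity of same-tumour arrays was tested exactly over 3003 choices of 2 pairs of arrays. Genes named are Smarca4 and Smarca2, and the 20 called genes with the largest SD over tumours. To these come the 3 largest differences called in each tumour, up to 4 called members of each list with the largest SD, and the 8 highest and 8 lowest mean ratios among genes 2-fold off in all 12 tumours. Genes named outside this rule are marked as chosen after their values were seen, or are members of lists that were called in a tumour. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

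The steps were tested on simulated data with 16474 genes. The F-test recovered 45% of 100 genes with an SD over tumours of 1 and 97% of 100 with an SD of 2, and called 3 of 16274 unchanged genes. These data had independent errors, with variances drawn from the kind of distribution that limma assumes. They held no shift shared by the second arrays, so the few false calls do not show how the F-test behaves under such a shift. The comparison of 1 tumour with 11 recovered 52% of 100 genes shifted by 2 and 88% of 100 shifted by 4, with 5 false calls. Camera with the fixed correlation found a list shifted as a whole and called none of 227 others when genes varied independently. When list members moved together without a shift, camera called 94 of 228 with the fixed correlation and 0 with the estimated one. How often the estimated correlation finds a shifted list was not measured. A call lost with it therefore does not show that a list was unshifted. Over 40 simulations without repeated tumours, centring genes on 12 tumours gave p under 0.05 for same-tumour arrays in 42.5%, and centring on 14 arrays in 2.5%.

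Alternatives were median centring, quantile normalization, stricter and looser filters on missing values, 1 probe per gene, single probes, a robust prior, first arrays only, leaving out second arrays or single tumours, other scores and other thresholds. Left out were a comparison with normal tissue or other genotypes, not analysed here, and a test against the reference, which is no control group. Chromosome and order of genes, used only in the closing observations, were taken from the gene table, and chromosomes are named by a gene that lies on them in that table. The separate value of 1 of these chromosomes is not reported here, while the counts include it.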

Results

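RNA from 12 mammary tumours of Brg1+/- mice was measured on 14 two-colour microarrays. Brg1, encoded by Smarca4, is the catalytic ATPase of the SWI/SNF chromatin remodelling complex, and these animals carried it in the heterozygous state. Each array held tumour RNA in Cy5 and a common mouse reference RNA in Cy3, and every value is read as the log2 ratio of tumour over reference, the base being inferred from the range of values. Tumours T172 and T284 each had a second array, marked biorep in the labels, and the other 10 tumours had 1 array each. The arrays carried values for 22501 to 22566 of 22575 probes, and the array medians lay between 0 and 0.018. The SD of the log2 ratios ranged from 0.995 for T55 to 1.271 for the first array of T284. All tumours had the same genotype and no control tissue was compared, so the comparisons were those between tumours. The labels do not say whether the tumours came from separate animals or what was repeated for the second arrays. The p-values below therefore describe only these samples, and the number of arrays limits their precision. Those of the F-test set tumours against the spread within a tumour, which rests on the second arrays of T172 and T284 alone. Those of Fisher's exact test treat genes as independent. Members of a list share the same arrays, and in most lists they moved together, so the Fisher p-values may be too small.

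The 2 arrays of a tumour resembled each other more than arrays of different tumours did. With the mean of each gene over the 12 tumours removed, the arrays of T172 correlated at r = 0.709 and those of T284 at r = 0.704, over 16474 genes that are not independent replicates. Across the 89 pairs of arrays from different tumours, r ranged from -0.465 to 0.616 with a median of -0.114. The highest of these, 0.616, joined the second arrays of T172 and T284. T160 with T55 (r = 0.439), T221 with T372 (0.390) and T135 with T2023 (0.382) followed among other tumours. The mean of the same-tumour pairs, 0.706, was the highest among 3003 choices of 2 pairs of arrays (exact one-sided permutation p = 0.000333, highest other choice 0.583). In simulated data without pairs this centring favoured arrays of the same tumour. With the mean over all 14 arrays removed instead, a setting chosen after seeing the data, the mean was 0.640 and again the highest of 3003 (highest other choice 0.561).

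**Figure D1:**
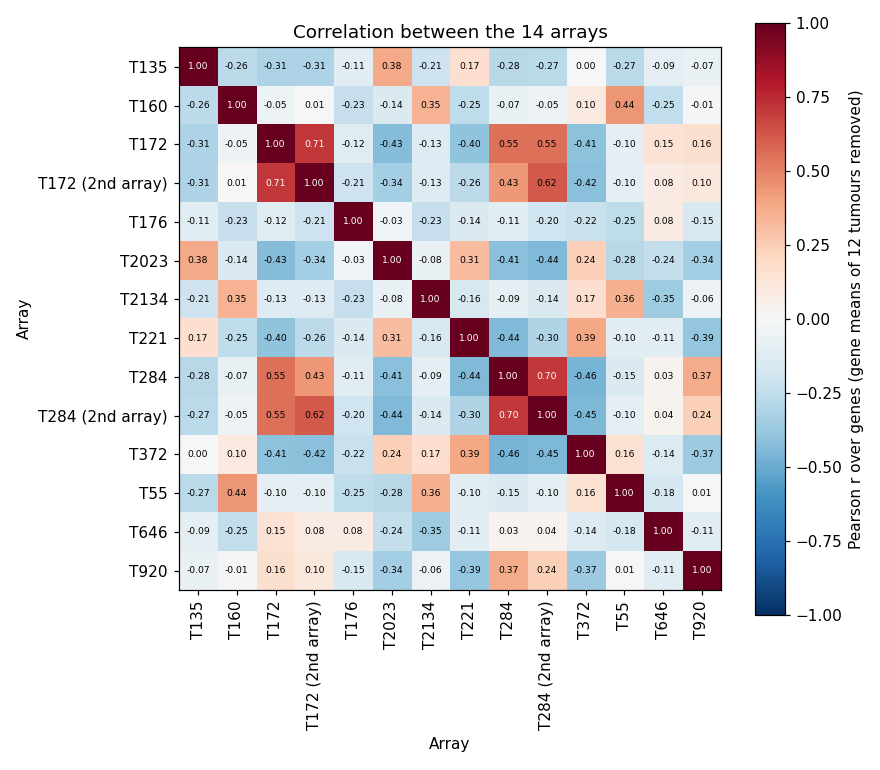
Pearson correlation over genes between each pair of the 14 arrays, with both axes listing the arrays by tumour and the colour and printed number giving r (no unit) after the mean of each gene over 12 tumours was removed. The arrays of T172 (r = 0.709) and of T284 (r = 0.704) show the highest correlations off the diagonal.

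Smarca4 transcript lay slightly below the reference RNA in 11 of the 12 tumours, with a mean log2 ratio of -0.60 ± 0.35 (SD, n = 12). Its lowest value was -1.08 in T284 and its highest 0.07 in T176. Smarca2, which encodes the alternative ATPase Brm, had a mean of -0.54 ± 0.43 (SD, n = 12), with -1.39 in T2134 and 0.12 in T176. Neither gene was called as different between tumours (limma adjusted p = 0.359 for Smarca4 and 0.365 for Smarca2). Each was measured by 2 probes whose means differed. The Smarca4 probes averaged -0.83 ± 0.55 and -0.37 ± 0.46 (SD, n = 12). The first lay below the reference in every tumour, and the second above it in T135 (0.01), T176 (0.23) and T920 (0.57). In T284 they stood at -2.04 and -0.12, so the tumour with the lowest value depends on averaging them. The Smarca2 probes averaged -0.84 ± 0.58 and -0.24 ± 0.39 (SD, n = 12). The reference RNA is not a normal control tissue, so these ratios do not measure the effect of the lost allele. Among 20 measured SWI/SNF subunit genes, 1 differed between tumours, and 1 did when adjusted over the list alone. That gene was Smarcd3, encoding the accessory subunit Baf60c, with 0.72 in T176 and -3.23 to -2.32 in the other 11 tumours (limma adjusted p = 0.00537). Without T176 it was no longer called (adjusted p = 0.617). The list held no more called genes than the rest of the array (Fisher's exact test, adjusted p = 0.182; fewer after quantile normalization, adjusted p = 0.0485), and its members were barely correlated over tumours (mean pairwise r = 0.018).

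Many genes differed between tumours by more than the 2 arrays of a tumour differed. The genes with the widest spread included casein genes, several genes of keratinised epithelium and hair, and Ibsp, a bone matrix sialoprotein. Csn1s2a, an alpha casein, ranged from -2.58 in T135 to 7.30 in T372, with an SD over tumours of 3.68 and a within-tumour SD of 1.21. Ibsp stood at 5.73 in T176 and 0.28 in T2023 against -5.07 to -4.08 in the other 10 tumours. Aqp3, a water and glycerol channel of stratified epithelium, ranged from -4.14 in T172 to 5.37 in T221. Comp, a cartilage matrix protein, was high in T172 (4.33), T646 (4.13) and T284 (3.63) and at most 0.52 elsewhere. The calprotectin genes S100a8 and S100a9 stood at 3.31 and 1.95 in T221 and at -5.17 and -6.16 in T172. Krt28 and Krt27, keratins of the hair follicle, peaked in T372 at 4.25 and 4.60, and Sostdc1, a secreted BMP and Wnt antagonist, in T2023 at 3.37. The remaining 11 of the 20 genes with the largest SD (2.78 to 3.07) included Crct1, Sprr2d, Rptn, Klk7, Kprp, Krtdap and Cnfn, which cornifying epithelium expresses. The others among these 11 were Calm4, Csn2, Stfa3 and Cwh43. In all, 3104 of 16877 genes were called by limma's moderated F-test at an adjusted p under 0.05. Of these, 1326 had an SD over tumours of at least 1, and 1590 of the 16877 genes passed at 0.01. The median gene had an SD over tumours of 0.386 and a moderated SD within a tumour of 0.306, which rests on the second arrays of T172 and T284 alone. Csn1s2a lost its call with a robust prior (adjusted p = 0.0826).

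Basal and squamous epithelial genes moved widely and together. All 14 measured basal genes were called over all genes and 14 when adjusted over the list alone, against 18.3% of other genes (Fisher's exact test, adjusted p = 3.13e-10). Trp63, the transcription factor of basal and stratified epithelium, stood at 3.57 in T221, 3.21 in T2023 and 2.41 in T135 but at -3.15 in T172 and -2.96 in T646 (SD 2.54, n = 12). The basal keratins Krt14 and Krt5 were highest in T2023 (2.93 and 1.96) and lowest in T172 (-2.60 and -3.61), and Id4 ranged from -3.55 in T284 to 2.87 in T135. Of 15 squamous genes 13 were called, and 13 when adjusted over the list alone (adjusted p = 7.42e-08). Krt16, a keratin of activated epidermis, ranged from -1.44 in T920 to 4.64 in T372, and Sprr1a, a cornified envelope precursor, from -1.64 in T284 to 4.11 in T135. Klk7, a protease of the cornified layer, ranged from -5.26 in T172 to 3.49 in T372, and Lgals7 from -3.76 in T646 to 3.20 in T221. Smooth muscle contractile genes, which myoepithelial cells also express, had 5 of 10 members called, and 5 over the list alone (adjusted p = 0.0316). Cnn1 ranged from -5.14 in T172 to -0.96 in T221, Tagln from -3.19 in T176 to 0.26 in T221, and Lmod1 was highest in T172 at 2.27. Myh11 stood at -0.10 in T920 and lost its call without that tumour (adjusted p = 0.268).

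Luminal and junction genes had their lowest list scores in T176. Krt18, a keratin of simple epithelium, stood at 1.14 to 2.97 in 11 tumours and at -4.25 in T176, and Krt8, its partner, at -3.53 in T176. Krt19 ranged from -4.12 in T176 to 2.72 in T2134, and Elf5, a regulator of alveolar luminal cells, from -2.23 in T176 to 4.83 in T55. Of 14 luminal genes 12 were called, and 12 when adjusted over the list alone (Fisher's exact test, adjusted p = 2.93e-07). Of 19 junction and epithelial adhesion genes 17 were called, and 18 over the list alone (adjusted p = 3.13e-10). Without T176, Krt18 (adjusted p = 0.0991) and St14 (0.905) were no longer called, whereas Epcam, Cdh1 and Tjp3 were. Mesenchymal genes had 11 of 15 called, and 12 over the list alone (adjusted p = 1.25e-05). Snai2 ranged from -3.82 in T172 to 1.28 in T2023, S100a4 from -2.54 in T172 to 2.82 in T176, and Cdh11 from -4.35 in T2134 to 1.5 in T176. Cdh2, N-cadherin, was 2.05 in T176 and lost its call without that tumour (adjusted p = 0.2). Fibroblast and matrix genes had 17 of 19 called, and 19 over the list alone (adjusted p = 3.13e-10). Col1a2 ranged from -3.85 in T920 to 2.17 in T176, Fap from -2.87 in T2134 to 2.82 in T176, Col5a1 from -4.15 in T920 to 1.33 in T176, and Col5a2 from -3.23 in T172 to 2.26 in T176.

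Milk genes and markers of immune cells and fat also differed between tumours. Of 12 milk protein and secretion genes 10 were called, and 10 over the list alone (Fisher's exact test, adjusted p = 5.45e-06). The milk score differed by 1.48 between the arrays of T172 and by 0.53 between those of T284, against a median difference of 1.57 between tumours. Milk was not alone in this. The arrays of T172 differed by 0.38 in smooth muscle (median between tumours 0.42), 0.46 in hypoxia (0.57) and 0.28 in skeletal muscle scores (0.35). Those of T284 differed by 0.22 in the junction score (0.28). In every list both same-tumour differences were smaller than the median between tumours. Csn2, beta casein, stood at 7.42 in T2134 and 6.90 in T55 but at -0.57 in T2023 and 0.07 in T135. Csn1s1 ranged from 0.09 in T176 to 6.97 in T372, and Glycam1 from -1.78 in T284 to 5.08 in T372. Glycam1 lost its call with a robust prior (adjusted p = 0.156). Interferon-response genes had 13 of 15 called, and 13 over the list alone (adjusted p = 7.42e-08), with Ifit1 at 3.04, Usp18 at 3.71, Mx2 at 4.39 and Isg15 at 3.76 in T920. In T176 the same 4 genes stood at -1.83, -0.89, 0.45 and -0.14. Macrophage genes had 9 of 15 called, and 13 over the list alone (adjusted p = 0.000702). Lyz2, lysozyme of myeloid cells, was 3.34 in T135, and Ctss, Mrc1 and Cd14 were lowest or next to lowest in T176 at -0.43, -2.63 and 1.23. Lymphocyte genes had 7 of 15 called, and 9 over the list alone (adjusted p = 0.0167). The T cell genes Cd3d, Cd8a and Cd8b1 were highest in T646 (1.53, 1.51 and 0.89) and the B cell gene Cd79b in T372 (2.08). Cd8a lost its call without T646 (adjusted p = 0.135). Adipocyte genes had 7 of 12 called, and 8 over the list alone (adjusted p = 0.00372). Plin1, which coats lipid droplets, and Cidec were highest in T221 at -2.22 and -1.79, Cd36 in T55 at -0.67, and Slc2a4 in T176 at -2.02. Without T221, Cidec was no longer called (adjusted p = 0.0974). Endothelial genes had 3 of 13 called, Cd34, Emcn and Robo4, and 3 over the list alone, not called as more than other genes (adjusted p = 0.718). All 3 were highest in T221, at 0.27, 0.33 and 0.24, and Robo4 lost its call without it (adjusted p = 0.127). Skeletal muscle genes had 4 of 15 called, and 6 over the list alone, not called as more than other genes (adjusted p = 0.528, but 0.0489 with 1 probe per gene). The fast myosin Myh4 stood at 2.97 in T55 and -4.97 to -0.81 in the others. Without T55, Myh4 (adjusted p = 0.177), Actn3 (0.130), Myh2 (0.261) and Pvalb (0.233) were not called.

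Proliferation genes had their lowest score in T646, although that list difference was not called with an estimated correlation (adjusted p = 0.256) and none of its 25 genes was called in T646 over all genes. Birc5, Cdc20, Rrm2 and Bub1, which act in mitosis or in nucleotide supply, stood at -2.65, -2.08, -2.38 and -2.42 in T646 and between -1.35 and 1.04 elsewhere. Of 25 proliferation genes 13 were called, and 16 over the list alone (Fisher's exact test, adjusted p = 0.000321), but none of the 25 at an adjusted p under 0.01. The members moved together more than those of any other list (mean pairwise r = 0.744). Without T646, Birc5 (limma adjusted p = 0.274), Cdc20 (0.0884), Rrm2 (0.203) and Bub1 (0.159) were not called. Hypoxia and glycolysis genes had 9 of 15 called, and 12 over the list alone (adjusted p = 0.000702). Ndrg1, Vegfa and Adm were highest in T2023 at 3.27, 2.46 and 3.43, and Slc2a1, the glucose transporter Glut1, in T221 at 2.96. Immediate early and heat shock genes, which respond to tissue handling, had 6 of 14 called, and 6 over the list alone (adjusted p = 0.0381). Nr4a1 and Ier3 were highest in T172 at 2.76 and 5.08, Egr2 in T372 at 2.89 and Hspa1a in T2023 at 1.80. Targets of p53 had 5 of 16 called, and 6 over the list alone, not called as more than other genes (adjusted p = 0.218). Perp ranged from -2.06 in T176 to 3.40 in T2023, Pmaip1 reached 3.81 in T221, Gadd45a 2.77 in T646 and Phlda3 2.05 in T2023. Members of most lists moved together, which Fisher's exact test does not take into account, so the following counts of lists may be too high. Of the 19 lists, 15 held more called genes than the rest of the array, and 15 did without T176, a setting chosen after seeing the data. With calls at an adjusted p under 0.01 the smooth muscle, lymphocyte, proliferation, and immediate early lists no longer did (adjusted p = 0.0885, 0.208, 0.208 and 0.0577). The smooth muscle list also lost its call with genes measured on all 14 arrays (0.0950), the immediate early list after quantile normalization (0.142), and the lymphocyte list with 1 probe per gene (0.199).

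**Figure D2:**
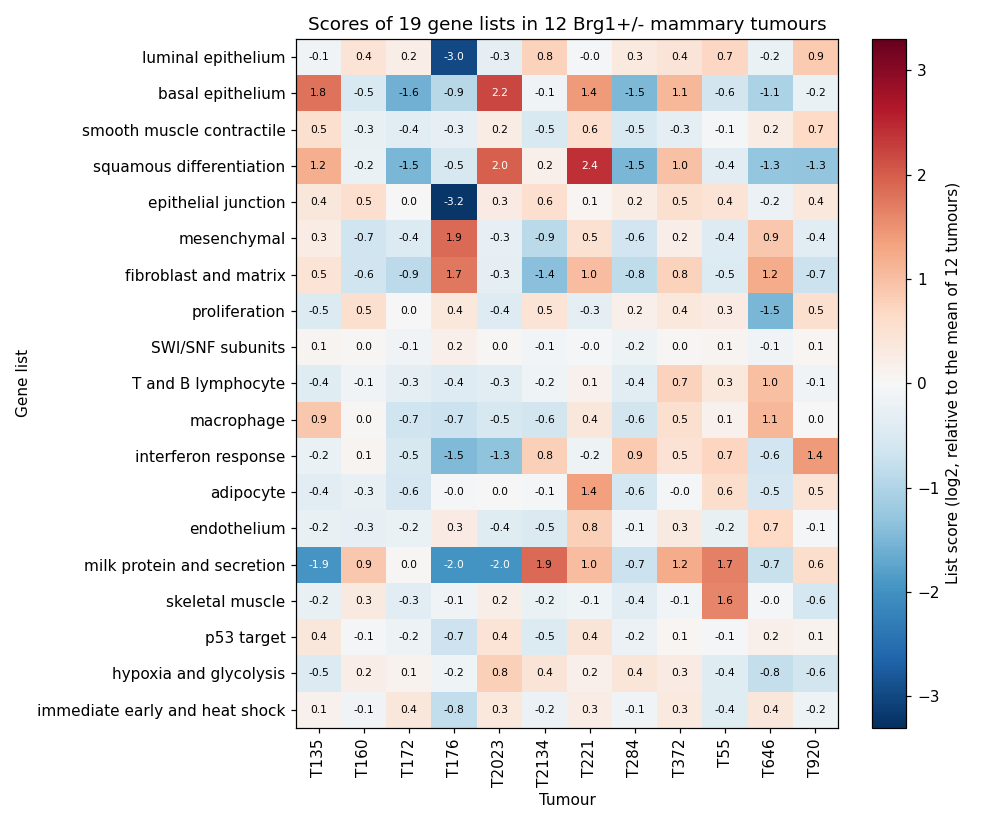
Scores of the 19 gene lists (vertical axis) in the 12 tumours (horizontal axis), where each score is the mean log2 ratio of the list's members after the mean of each gene over the 12 tumours was removed. T176 has the lowest luminal (-2.97) and junction (-3.22) scores, T646 the lowest proliferation score (-1.51), and T55 the highest skeletal muscle score (1.62).

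T176 stood furthest from the rest when each tumour was set against the other 11. In it 643 genes were called, 417 higher and 226 lower. Ibsp was higher by 9.83 ± 1.38 (SE, 1 tumour against 11; limma adjusted p = 0.00102), Omd, a small proteoglycan of bone, by 7.64 ± 0.81 (adjusted p = 0.000117), and Cgref1 by 6.87 ± 1.03 (adjusted p = 0.00153). Of 19 junction genes 14 were lower in T176, and 14 when adjusted over the list alone, with a mean difference of -3.52 over the list. Epcam stood at -4.09, the adhesion gene Cdh1 (E-cadherin) at -4.58, the membrane protease gene St14 at -3.10 and Tjp3 at -2.79. This list was called with camera (adjusted p = 3.68e-27) and with an estimated correlation (adjusted p = 0.00398 with an estimated correlation). Of 14 luminal genes 7 were lower, among them Krt18, Krt8, Gata3 and Kit, and Esr1 was higher, with 8 lower and 1 higher when adjusted over the list alone. The luminal mean difference was -3.23 (camera adjusted p = 3.79e-09; adjusted p = 0.0520 with an estimated correlation). Among mesenchymal genes Cdh2, Cdh11, Snai1 and Twist1 were higher, 4 of 15 and 7 over the list alone, and among matrix genes 6 of 19 were higher, and 9 over the list alone, including Col1a2 and Fap. Neither list kept its camera call (both adjusted p = 0.903 with an estimated correlation), with mean differences of 2.04 and 1.91. In the same tumour markers of other cell types stood at -0.77 (macrophage), -0.46 (lymphocyte), -0.05 (adipocyte) and 0.29 (endothelium) relative to the other 11. The immediate early and heat shock score was lowest in T176 (-0.81, against -0.41 to 0.38 in the others), as were the interferon (-1.46) and p53 target (-0.69) scores, but the camera calls of these lists were lost (all adjusted p = 0.903 with an estimated correlation). Members of other lists that were called in T176 were Smarcd3, Pparg, Cd68 and P4ha1, which were higher, and Itgb4, Jun and Irf9, which were lower. Over all 12 tumours 797 such calls were made, and 159 without T176. T176 also had the lowest correlations with other arrays before genes were centred, down to 0.465.

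Far fewer genes set apart each of the other 11 tumours, 154 calls in all, and most of these concerned single genes. In T2134 the calls included the amylases Amy2 (higher by 6.50 ± 0.60, SE; limma adjusted p = 0.000349) and Amy1 (6.57 ± 0.86), whose near-identical sequences a single probe may not tell apart, and Bpifa2 (6.17 ± 1.03), a salivary secretory protein. Of its 18 calls 14 were higher. Dnase1, Pip, Prb1, Klk1b5 and Klk1b8, which salivary or lacrimal glands also express and which were singled out after their values were seen, were among them. Bpifa2 lost its call when any 1 of 10 other tumours was left out (adjusted p = 0.0521 to 0.101) and kept it without T372. It was also lost with genes measured on all 14 arrays (0.0547) and with a robust prior (0.0553). In T221 24 genes were called, led by Serpinb3d (5.94 ± 0.39, adjusted p = 2.83e-05) and Serpinb3c (6.23 ± 0.96), serpins of squamous epithelium, and Gsta1 (6.73 ± 0.83). Without T160 the count was 12 and Serpinb3c was not called (adjusted p = 0.0607). The squamous score was highest in T221 (2.42), as were the adipocyte (1.37) and endothelial (0.80) scores. The camera calls of these lists were lost (adjusted p = 0.903, 0.426 and 0.903 with an estimated correlation), and over the list alone 5 of 15 squamous and 6 of 12 adipocyte genes were higher. In T372 10 genes were called. They included Krt75 (4.24 ± 0.58), a hair follicle keratin, and Krtap14 (3.76 ± 0.50) and Krtap15 (3.69 ± 0.53), keratin-associated proteins of hair. The count for T372 was 21 without T2023, 6 without T172, and 5 without each of T2134, T284, T55 and T646. Krtap15 lost its call without T172, T2134, T284, T55 or T646 (adjusted p = 0.0557 to 0.0716) and after quantile normalization (0.0934).

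T55 carried skeletal muscle genes, and T646, T920 and T135 each had a small set of their own. In T55 the skeletal muscle list lay 1.76 above the other tumours (camera adjusted p = 2.85e-29; adjusted p = 0.00997 with an estimated correlation), with 1 of 15 members called over all genes and 9 when adjusted over the list alone. Myot, of the sarcomeric Z disc, was higher by 3.95 ± 0.46 (SE; limma adjusted p = 0.00505) and Pvalb, a calcium buffer of fast fibres, by 3.05 ± 0.47, while Hdx was lower (-2.68 ± 0.27). In T55 13 genes were called, 8 without T2134 and 25 after quantile normalization, and Pvalb lost its call without T135, T172, T2134, T221, T284 or T646 (adjusted p = 0.0513 to 0.0674). The milk score of T55 was also high (1.68), but its camera call was lost (adjusted p = 0.903 with an estimated correlation). In T646 proliferation genes differed from the others by -1.65 as a list mean (camera adjusted p = 7.06e-32; adjusted p = 0.256 with an estimated correlation). None of the 25 was called over all genes and 21 were lower over the list alone. Lymphocyte genes in T646 lay 1.09 higher (adjusted p = 0.663 with an estimated correlation; 5 of 15 over the list alone) and macrophage genes 1.20 higher (adjusted p = 0.903 with an estimated correlation). Matrix (1.34), mesenchymal (0.96) and endothelial (0.73) lists also lay higher in T646 and hypoxia genes lower (-0.87), and none of these was called (all adjusted p = 0.903 with an estimated correlation). Among 16 called genes in T646 were Foxa3 (4.45 ± 0.64), an endoderm transcription factor, Pde2a (3.60 ± 0.57) and Celf4 (3.46 ± 0.46). The count for T646 was 5 without T160 or T372, 6 without T2134, T55 or T920, 9 without T172, and 5 from first arrays only. Foxa3 lost its call without T160, T2134, T372 or T55 (adjusted p = 0.0541 to 0.0722), and Pde2a without T160, T172, T2134, T284, T372, T55 or T920 (0.0565 to 0.0813). First arrays only also ended both calls (0.0524 for Foxa3 and 0.0663 for Pde2a). In T920 37 genes were called, led by Tex11 (4.46 ± 0.44, adjusted p = 0.00153) and by the growth factor genes Fgf8 (3.80 ± 0.40, adjusted p = 0.00184) and Wnt10b (3.32 ± 0.58, adjusted p = 0.0436). Its count was 18 without T372, 21 without T55, 23 without T160, 24 without T2023 and 16 after quantile normalization. Wnt10b lost its call when any 1 of 10 other tumours was left out (adjusted p = 0.0539 to 0.0799) and kept it without T176. It was also lost after quantile normalization (0.109) and from first arrays only (0.0506). The interferon score was highest in T920 (1.42; camera adjusted p = 0.00043, and 0.903 with an estimated correlation), with 1 gene called over the list alone. In T135 10 genes were called, among them Gpat2 (3.37 ± 0.24, adjusted p = 7.35e-05), Vmn1r4 (-3.17 ± 0.26) and Cdx4 (-3.87 ± 0.49). The count for T135 was 6 without T160 and 18 without T2023 or T920, and 16 after quantile normalization.

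The remaining tumours T172, T284, T2023 and T160 had 9, 10, 6 and 1 called genes. In T172 Nras, a small GTPase and known oncogene, was higher by 3.70 ± 0.39 (SE; limma adjusted p = 0.00214), the kallikrein Klk1b11 by 4.65 ± 0.59 and the oestrogen sulfotransferase Sult1e1 by 4.51 ± 0.61. In T284 Irf2bp2 was lower (-2.85 ± 0.32), and Mknk2 (2.74 ± 0.33) and Plekhd1 (3.05 ± 0.43) were higher. T172 and T284 resembled each other, and the count for T172 was 30 without T284, and that for T284 was 37 without T172. The count for T172 was 14 without T2134 and 22 from first arrays only. For T284 it was 19 from first arrays only, 5 without T160 or T646, 6 without T2134 and 4 without T372. Plekhd1 lost its call without T160, T372 or T646 (adjusted p = 0.0506 to 0.0593), and after quantile normalization T284 had 1 call, with Mknk2 (0.0556) and Plekhd1 (0.0833) among those lost. In T2023 Skint3 (2.79 ± 0.37) and Col6a4 (2.95 ± 0.40), a collagen VI chain, were higher and the olfactory receptor gene Olfr630 was lower (-3.06 ± 0.38). The count for T2023 was 17 without T135, 2 without T646, and 0 without T160, T172 or T55, where Olfr630 (adjusted p = 0.05 to 0.0587), Skint3 and Col6a4 lost their calls. Col6a4 was also lost without T221 (0.0519) and T646 (0.0571), and Skint3 without T646 (0.0565). The single call of T160, the vomeronasal receptor gene Vmn1r198 (-2.57 ± 0.32, adjusted p = 0.0393), was lost without any 1 of 9 other tumours (0.0523 to 0.106), and the count was 2 without T372. Olfactory and vomeronasal receptor genes made up 21 of the 154 calls outside T176 (13.6%) and 5.08% of the genes tested. Camera called 74 of 228 combinations of list and tumour, of which 2 held with an estimated correlation, junction genes in T176 and skeletal muscle genes in T55. In simulated data whose list members moved together without any shift, the fixed correlation gave 94 calls of 228 and the estimated one 0. How many shifted lists the estimated correlation misses was not measured.

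**Figure D3:**
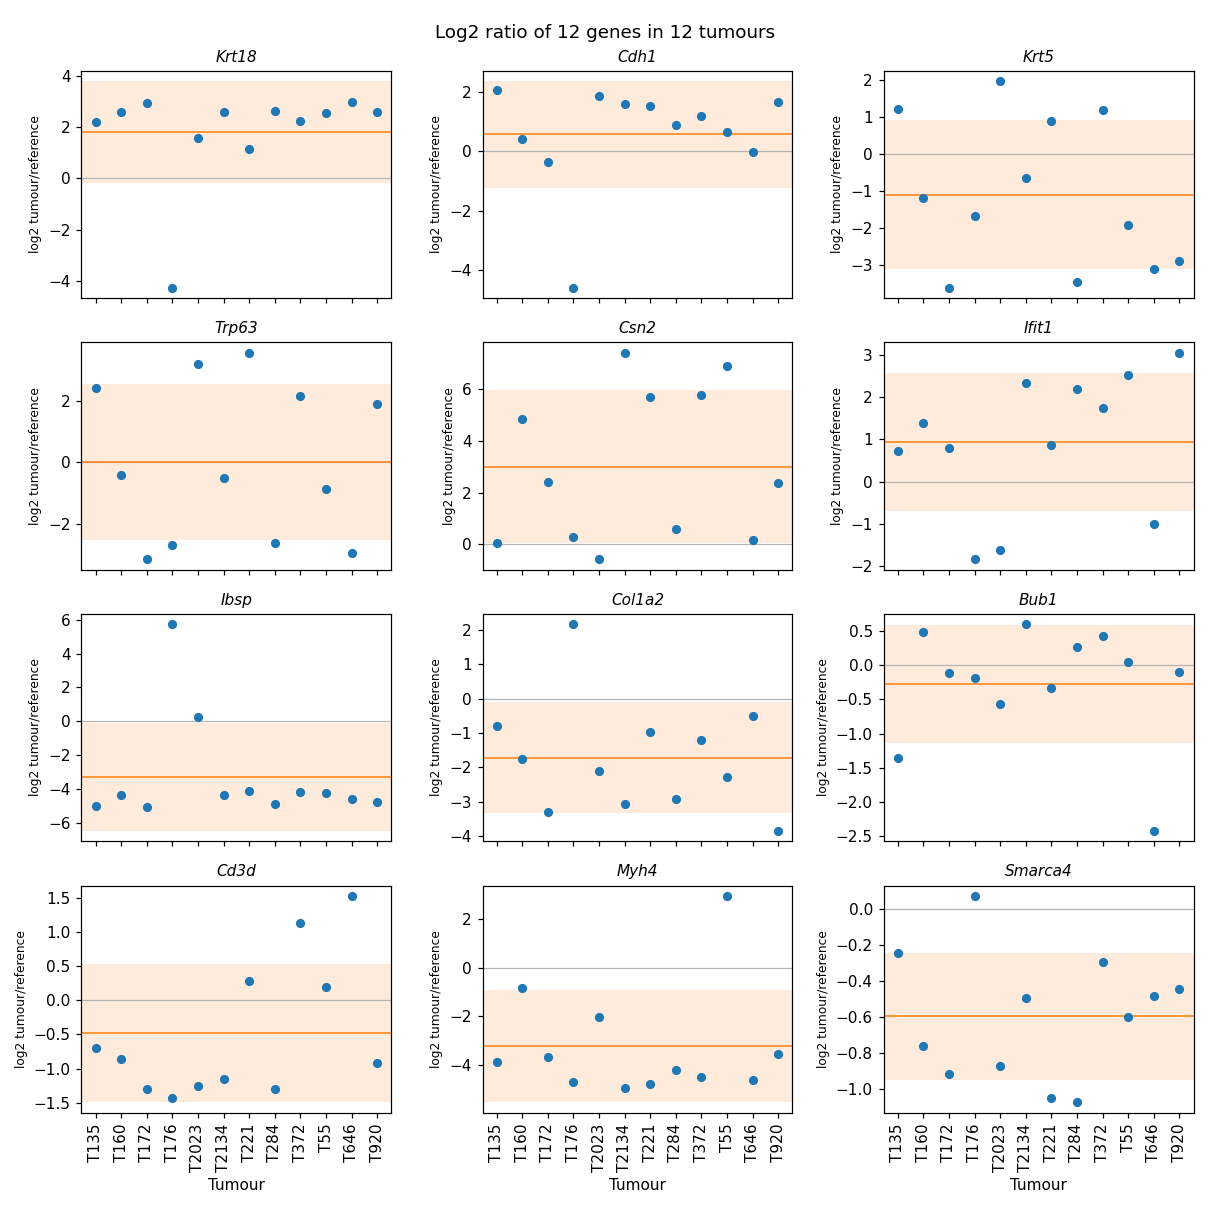
Log2 ratio of tumour over reference (vertical axes) for 12 genes in the 12 tumours (horizontal axes), with 1 point per tumour, the orange line at the mean and the band at 1 SD over tumours. Krt18 (-4.25) and Cdh1 (-4.58) were lowest and Ibsp (5.73) highest in T176, while Smarca4 stayed between -1.08 and 0.07 over all tumours.

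Against the reference RNA, 21 genes were at least 2-fold above and 795 at least 2-fold below in all 12 tumours, of 16571 genes measured in all. Among the genes above, Mmp3, a matrix metalloproteinase, had the highest mean at 4.41 ± 1.72 (SD, n = 12), followed by the chemokine gene Ccl8 at 3.99 ± 1.29 and the activin subunit gene Inhbb at 3.55 ± 1.38. Cd14 (3.19 ± 1.01), St8sia6 (3.06 ± 1.18), the immunoproteasome gene Psmb8 (3.03 ± 0.70), B2m (2.94 ± 0.79), which pairs with MHC class I, and Ier3 (2.90 ± 1.23) came next among them. The lowest of the genes below were Fabp1, a fatty acid binding protein of liver and gut, at -8.35 ± 0.53, Atp1b4 at -7.81 ± 0.38 and the fibrinogen gene Fgg at -7.50 ± 1.01. Itm2a (-7.34 ± 0.73), the urea cycle gene Cps1 (-7.31 ± 0.42), Myot (-7.18 ± 1.22), Apoh (-7.04 ± 0.70) and Ambp (-6.84 ± 0.58) followed. Without T176, a setting chosen after seeing the data, 97 genes lay above. The reference is a common RNA rather than a control group and the dyes were not swapped, so no test was made and a dye effect on single genes cannot be separated from the ratio.

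Mesenchymal and matrix scores moved together over the 12 tumours, as did basal and squamous scores. Mesenchymal with matrix gave Pearson r = 0.951 (permutation p = 1e-05, the smallest that 100000 resamples can give; adjusted p = 0.00015) and Spearman rho = 0.930 (permutation p = 4e-05; adjusted p = 0.0006). Basal with squamous gave r = 0.922 (p = 9e-05; adjusted p = 0.00067) and rho = 0.902 (p = 0.00019; adjusted p = 0.00142). Without the 2 tumours farthest from the median of the first score these values were r = 0.969 and 0.912. Junction scores ran against mesenchymal scores (r = -0.813, p = 0.00282, adjusted p = 0.0141; rho = -0.636, p = 0.0295, adjusted p = 0.0924) and matrix scores (r = -0.619, p = 0.00752, adjusted p = 0.0282; rho = -0.469, p = 0.128, adjusted p = 0.273). Without T176 and T646, the tumours farthest from the median junction score, these were -0.306 and -0.156. Without T176 alone both were weaker and not called (r = -0.590, adjusted p = 0.141, and r = -0.442, adjusted p = 0.371). Without T646 alone neither was called either, but r was no weaker (-0.849, adjusted p = 0.0869, and -0.649, adjusted p = 0.108). The relation to the matrix score also lost its call without T2134 (r = -0.614, adjusted p = 0.0551) or T221 (r = -0.662, adjusted p = 0.0522), with r close to that of all 12 tumours. Lymphocyte with macrophage scores gave r = 0.687 (p = 0.0125, adjusted p = 0.0376) and rho = 0.622 (p = 0.0358, adjusted p = 0.0924). Without T372 and T646 r was 0.374, and without each alone 0.664 and 0.512. The relation was not called when any 1 of 10 tumours was left out (r = 0.512 to 0.692, adjusted p = 0.0522 to 0.198), nor after quantile normalization (0.0621), with 1 probe per gene (0.0547), or with median (0.105) or scaled (0.131) scores. Over all single tumours left out, r ranged from 0.512 to 0.930. Luminal with proliferation scores gave r = 0.143 (p = 0.629, adjusted p = 0.901) but rho = 0.734 (p = 0.00834, adjusted p = 0.0417), and without T176 r was 0.834 (adjusted p = 0.0011). Smarca4 was not called with Smarca2 (r = 0.066, p = 0.837; rho = 0.014, p = 0.974), proliferation (r = 0.096, p = 0.769; rho = 0.175, p = 0.586) or junction genes (r = -0.522, p = 0.0801; rho = 0.077, p = 0.818). Smarca2 with proliferation gave r = -0.493 (p = 0.1; rho = -0.615, p = 0.0370, adjusted p = 0.0924). All p-values are two-sided permutation values over 15 relations, of which 5 passed with Pearson's r after Benjamini-Hochberg adjustment. The count was 2 without T646 and 3 without T176, T2134 or T221. The labels name no batches within which the relations could be computed again.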

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

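Centring on 14 arrays and the counts of lists and of reference levels without T176 were settings chosen only after the results were seen. The number of genes that differed between tumours ranged from 2653 (single probes) to 4191 (quantile normalization) over the other planned settings and was 1590 at an adjusted p under 0.01, by the stricter threshold itself. It was 3980 and 3241 without the second array of T172 and of T284, and 2520 without T176 to 3293 without T160. Named genes kept their side of the threshold in 2405 of 2448 recomputed results, and named genes in single tumours in 536 of 612. After quantile normalization the counts were 16 for T135, 1 for T284, 25 for T55 and 16 for T920. From first arrays only they were 22 for T172, 19 for T284 and 5 for T646. The cause of these shifts was not tested. Leaving out 1 other tumour at a time gave 159 (without T176) to 807 calls over all tumours, 6 to 18 for T135, 0 to 2 for T160, 9 to 30 for T172, 538 to 700 for T176, 0 to 17 for T2023, 12 to 18 for T2134, 12 to 36 for T221, 4 to 37 for T284, 5 to 21 for T372, 8 to 17 for T55, 5 to 23 for T646 and 18 to 45 for T920. Camera calls went from 74 to 2 with an estimated correlation, which widens the test where members move together, and stayed between 67 and 80 without single tumours. At an adjusted p under 0.01 the share of called genes was 0% for proliferation and 7.69% for endothelium, at or below other genes. The similarity of same-tumour arrays stayed past its exact test in all 9 other settings tried. Among these, median centring and the stricter and looser filters on missing values could only return the main value of 0.706. A constant per array leaves Pearson's r unchanged, and only genes with values on all 14 arrays entered. Mean correlations ranged from 0.549 (Spearman, exact permutation p = 0.000333) to 0.919 (uncentred, exact permutation p = 0.000666). As a root-mean-square Euclidean distance, where smaller is closer, the mean was 0.516 (exact permutation p = 0.00167). By that distance 5 of 3003 choices, the real one included, were as close or closer. Uncentred, 1 other choice of pairs was as high.

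Relations passing with Pearson's r numbered 4 or 5 under other settings and 2 (without T646) to 5 without single tumours. Relations that changed sign were not called in any setting. Smarca4 with proliferation was -0.108 with 1 probe per gene and ranged from -0.021 (without T176) to 0.312. Adipocyte with junction scores was -0.042 with scaled members. Without single tumours, luminal with basal scores ranged from -0.418 (without T176) to 0.123 and proliferation with hypoxia from -0.203 (without T646) to 0.536. Lymphocyte with interferon ranged from -0.0059 (without T176) to 0.401, adipocyte with endothelium from -0.208 (without T221) to 0.618, Smarca4 with Smarca2 from -0.322 (without T176) to 0.217, and Smarca4 with junction scores from -0.595 (without T372) to 0.370 (without T176). The cause was not tested beyond the tumour named. With 2-fold required in 10 of 12 tumours, 208 genes lay above and 1331 below the reference, and 97 lay above in the 11 tumours without T176, since each rule asks less. A filter of at least 7 arrays removed no tested gene and changes nothing. Signal over background is not part of the ratios, so its limits could not be set.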

Other observations

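The tests of cell shares and Y-linked genes in T176, of chromosomes and of other pairings of arrays were chosen only after the results were seen, as were the additional gene lists used here. Genes of bone-forming cells were high in T176. Of 15 measured osteoblast genes from a list written after Ibsp and Omd had been seen, 13 were at least 2-fold above the mean of the other 11 tumours and 9 were called higher with limma. Panx3 lay 6.70, Phex 6.15, Mmp13 5.79 and Col24a1 5.45 above the other tumours on the log2 scale. Of 13 osteoclast genes 8 were called higher, among them the proteases Mmp9 and Ctsk (both 6.24) and the phosphatase Acp5 (4.09), with a median over the list of 2.18. Other members of this list stayed within 2-fold of the other tumours, namely Tnfrsf11a (-0.59), Itgb3 (-0.43), Calcr (-0.10), Clcn7 (0.25) and Oscar (0.47). Genes of cartilage were not raised as a list, with a median of -0.28 over 12 genes, Acan 2.31 above and Col9a3 at -3.67 relative to the others. Of the osteoblast genes 2 lay above the reference in the mean of the other 11 tumours, and none was in another list.

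Receptor and oncogene levels, also listed after the data had been seen, were called as different between tumours for some genes and not for others. Kit, a receptor of luminal progenitor cells, averaged 2.64 ± 1.43 (SD, n = 12; limma adjusted p = 0.00078) with -1.34 in T176. Egfr (adjusted p = 0.0341), Myc (0.0425) and the cell cycle inhibitor Cdkn2b (0.0403) were also called, with Egfr highest in T284 (1.71) and Myc in T2134 (2.49). Esr1 (0.419), Pgr (0.629), Erbb2 (0.707), Erbb3 (0.745), Met (0.302), Cdkn2a (0.809) and Brca1 (0.1) were not. A missing call does not mean a small spread, since Brca1 had an SD over tumours of 0.713 and Myc one of 0.691. Esr1 was higher in T176 when that tumour was set against the other 11. The casein genes Csn1s2a and Csn2 and the myosin gene Myh4, picked from the genes with the largest shared differences, were higher on both second arrays than on the first arrays of T172 and T284. For Csn1s2a the differences were 3.72 and 3.44, for Csn2 2.75 and 1.59, and for Myh4 2.45 and 1.80. The milk score also rose, from -0.70 to 0.77 in T172 and from -0.97 to -0.43 in T284. The skeletal muscle list did not share this, with -0.48 and -0.20 on the first and second array of T172 and -0.33 and -0.39 on those of T284.

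T176 stands apart from the other tumours in 643 genes, and bone genes lead them. A lower share of epithelial cells with every other cell type rising alike is argued against for the matrix and macrophage lists. They stood at 1.91 and -0.77 in T176 relative to the other 11, which is 2.68 ± 0.66 apart (SE over list members). Members of a list moved together, so this SE from 1 tumour may be too small. Of 107 probes at least 2 off in T176, 64.5% had another probe of the gene off the same way (30.0% to 83.3% in the other tumours). This argues against chance deviations of single probes. All probes lie on 1 array of 1 sample, so a deviation of the whole array could not be tested in T176. A piece of bone with its marrow stays open, since the median of -0.0701 over 18 marrow genes (mean -0.44 ± 0.34, SE) did not lie below the bound set beforehand by more than 2 SE and the members went both ways, from 1.81 for Mpo to -4.84 for Ltf. Bone-forming cells, whether of the tumour or next to it, stay a candidate explanation, with a median of 3.40 over the osteoblast genes against -0.32 to 0.26 for 95% of random lists. RNA from a male animal, or another sample under this label, also stays open, with Eif2s3y 4.15 above and Xist 3.20 below every other tumour. The nearest tumour for Xist was T2134 (-1.085), with T284 next at -1.01 as the mean of arrays at -2.30 and 0.29. Against the first array of T284 alone the gap of Xist is 1.98, under the bound of 2. Kdm5d lay only 1.01 above and Uty lay inside the range of the others; a first wording of the test, which asked this of all Y-linked genes, was not met and was replaced after that was seen.

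Second arrays of T172 and T284 differ from the first arrays in similar genes, with r = 0.324 between the 2 sets of differences over 16474 genes. With the tumours crossed r was -0.243. The difference between the tumours enters the 2 crossed sets with opposite signs, so this value is no control for the first. Of genes at least 2-fold off in both tumours, 71 were higher on both second arrays, 49 lower on both and 12 went opposite ways. Compression or stretching of ratios with the mean level of a gene over the 10 other tumours is argued against. After the mean difference at each such level was removed, r was still 0.338. A stretch that follows the own ratios of T172 and T284 would be left in by this step, so it was not tested. A batch of arrays or labellings stays a candidate explanation, with r = 0.216 among the 4119 genes that varied least over the 10 other tumours, just past the bound of 0.2 set beforehand. The labels give no batch, and no biological explanation was tested, so the within-tumour spread behind the F-test may hold a part shared by both second arrays.

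Single genes that stand apart in single tumours could be chance deviations of 1 array, which is argued against for genes called higher in T172 and T284. Of 41 genes called from the first arrays, 27 (65.9%) lay beyond all other tumours the same way on the second array, where 10.1% to 11.4% of all genes lay above all others. Most genes called higher were repeated in this way, but most genes called lower were not. The share of all genes below all others was not computed. The other 10 tumours have 1 array each, so this was not tested in them. Fgf8 and Wnt10b in T920 are known sites of retroviral insertion in mouse mammary tumours, which led to the hypothesis that such genes are switched on in single tumours. The other 17 listed genes had a mean largest upward deviation of 1.20, between the median (0.934) of random genes and the upper bound (1.38) of the middle 95% of them, which leaves the hypothesis undecided.

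Gains or losses of whole chromosomes in T172 and T284 may shift genes of a chromosome together. Over 15785 genes on 19 autosomes, 14 chromosome means in these tumours (10 in T172 and 4 in T284), taken over gene deviations limited to 0.5 either way on the log2 scale, passed permuted gene order with all 4 equal parts of the chromosome shifted the same way on both arrays. The largest of these limited means were those of the chromosomes carrying Vegfa (0.111), Src (0.106) and Myc (0.0929) in T172 and of those carrying Src (0.0884) and Myc (0.0862) in T284, and in T160 that of the chromosome carrying Apc (0.131). Of 228 combinations of chromosome and tumour 57 passed, and permuting gene order ignores that neighbouring genes are co-regulated, so a shift does not establish a copy number change.

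The 3104 genes that differ between tumours were counted again after other pairs of arrays were treated as the repeated tumours. Among 100 choices, the real one included, 1 gave as many genes, and the highest of the others gave 992. Treating arrays of different tumours as repeats adds differences between tumours to the within-tumour spread. The test is not independent of the correlation between arrays of the same tumour, which had been seen before. Lower counts for other pairs were to be foreseen from it, so the test does not decide whether chance pairing is the source.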
